A study of Oryza sativa Japonica Group with 12 samples.

How the data were processed

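Shoots of 1-week-old rice seedlings were labelled as the source, while the extraction protocol in the labels names leaf. The 12 libraries fell into 4 groups of 3, wild type ZH11 and osfkbp20-1b, each after mock or 100 µM ABA for 6 h. The 8 deposited tables held, for each of 4 pairwise comparisons, a full table of 349605 exon and intron features and a short table of introns that the authors called. Reads were counted with HTSeq and scaled with DESeq against IRGSP-1.0, per the submitters' processing notes; versions and the aligner are not given in the sources used here.

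Per the file headers, the coverage signal of each feature and library is a normalised count. Each deposited signal was a whole number of reads divided by 1 factor per library, to within 1e-06, and the factors equalled median-of-ratios factors recomputed here. The deposited count columns of osfkbp20-1b_ABA_2 and osfkbp20-1b_ABA_3 had a factor of 1 and so were read counts as they stand. The smallest deposited count was 1 read per feature, so features at 1 were treated as at the floor, and they made up 21.4% to 30.3% of features per library. The authors' retention ratio was the intron reads divided by the mean of the 2 flanking exons, and it exceeded 1 in some library for 22.7% of tested introns. The authors' p-value could be recomputed as a Welch test on that ratio. Their calls required p below 0.05, a fold above 1.5 and a normalised intron count of 20 in at least 1 library, as worked out from the deposited tables. The 6 columns of per-sample ratios in each table were not used here, because the ratios were recomputed from reads.

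Column headings number the libraries differently from the replicate numbers in the labels, so columns were assigned to groups only, and the letter N was taken as mock by elimination. No paired analysis was possible by the labels' replicate numbers because the heading numbers do not follow them. A fit paired by heading number was possible for the mock comparison only. The heading numbers 1, 2 and 4 recur in both mock groups. Correlations across genes of library deviations were 0.122, 0.194 and 0.291 for equal numbers and −0.226 to 0.0969 for the others, so a fit with that number as a term was added as an alternative.

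Introns were tested with limma 3.58.1 (trend) on log2 of TMM-normalised reads plus a pseudocount of 1, after edgeR's expression filter, with Benjamini-Hochberg adjusted p below 0.05. The plan written before the data were examined named edgeR's quasi-likelihood test on counts. The files hold normalised signal, and limma became the reported test, run on TMM-normalised values of the recovered reads. The tests of edgeR 4.0.16 and DESeq2 1.42.0 on the same recovered reads became alternatives. This departed from the plan, since the recovered reads also allowed the planned test. A second level tested the log2 ratio of intron reads to flanking exon reads where both averaged at least 10 reads. A further level, added after the files were seen, tested exon reads summed over the first-numbered transcript of each locus with a mean of at least 10 reads above the floor. The interaction was fitted over all 12 libraries. Folds from a group at the floor were bounded with 3 reads per library. Group means and SDs of named genes were TMM-normalised within the 6 libraries of a comparison; those of OsFKBP20-1b, of the interaction gene, of the plots and of medians per library were TMM-normalised over all 12.

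Named genes followed a rule fixed before the data were examined. OsFKBP20-1b came first, then among called introns with non-overlapping groups and at least 20 reads in the higher group the 8 largest rises and 8 largest falls, at most 1 per gene, then up to 4 per gene list with the smallest adjusted p, and 5 each way for the interaction. At most 4 undescribed genes were named by identifier per comparison. The same rule was applied to exon reads. Examples in the text that stand outside it, the storage protein genes and the copy of the LEA-18 gene, were chosen after their values were seen.

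Gene lists were matched by words in the descriptions that the tables give, since only 2 identifiers matched the reference of gene names, from another assembly, which was not used here. Lists fixed beforehand were ABA signalling core (33 members), ABA metabolism (2), LEA and dehydrin (36), SR proteins (29), spliceosome (49), FKBP and cyclophilin (47), heat shock and chaperones (201), photosynthesis (68), ribosomal proteins (321), stress transcription factors (138), nonsense-mediated decay (1), circadian clock (23) and other organs (97). A list of organelle genes, sought by chromosome name, matched 0 members. Genes on nuclear chromosomes described as ribulose bisphosphate carboxylase large subunit or photosystem II protein D1, proteins that plastids encode, took 3.12% (osfkbp20-1b_ABA_1) to 22.9% (WT_ABA_3) of reads. The D1 copy Os04g0473150 was in the photosynthesis list. Iron acquisition (16), root markers (9) and whole-word versions of ABA signalling (18), SR proteins (17) and clock (17) were added after the data were seen. The ABA signalling list wrongly caught genes such as NAS1 and NAS3, and the SR list a chloride channel-like gene (Os04g0644800), which the whole-word versions left out. Lists of at least 5 genes were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, adjusted over lists and comparisons. Expected overlaps were the product of the called counts over the number tested in both.

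Each step was tested on simulated data made from the real means and library sizes. For introns limma recovered 80%, 74.1%, 81.3%, 54.9% and 10.2% of simulated 4-fold changes for ABA in wild type, ABA in the mutant, genotype after mock, genotype after ABA and the interaction, on 18537, 20275, 21259, 16051 and 26848 introns. For genes, 4-fold recovery was 86.7%, 87.0%, 92.6%, 70.7% and 59.3%. False calls made up 8.43%, 4.41%, 2.5%, 2.04% and 0% of simulated intron calls, 9.68%, 4.96%, 9.94%, 7.45% and 5.26% of gene calls, and 11.9% of ratio calls for ABA in wild type (0% in the others), so several exceeded the 5% aimed for. Relative to exon reads 4-fold recovery was 38.3%, 14.7%, 56.7%, 9.32% and 0%. For this ratio intron and exon reads were simulated independently, while variation that both share in a real library can cancel. These shares may therefore differ from the recovery of ratio changes in the real libraries, which stays unknown. Simulated 2-fold changes were recovered, in the same order, in 22.1%, 32.4%, 62.9%, 5.95% and 8.70% of genes and 10%, 6.25%, 19.3%, 3.33% and 0% of introns. Relative to exon reads, with the limit just given, 2-fold recovery was 0.943%, 0%, 2.08%, 0% and 0%.

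Alternatives covered other scalings, other tests, filters, the pseudocount of 5, leaving out each library, libraries together in 1 fit, and the removal of libraries with unusual marker levels. Counting was not stated to use strand, so overlapping and antisense genes are uncertain. Near-identical genes such as the dehydrins, NAS1 and NAS2, thionin-like genes, glutelins and the LEA-18 pair may share reads and are uncertain too. Of 126849 distinct introns 27264 overlap an annotated exon of another transcript, where intron reads can be exon reads. Calculations used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.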

Results

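RNA sequencing measured the transcripts of rice shoots in wild type (cultivar ZH11) and in the osfkbp20-1b mutant, whose mutated gene encodes an immunophilin. Seedlings were 1 week old and received either a mock treatment or 100 µM abscisic acid (ABA), a drought hormone, for 6 h. Each of the 4 groups held 3 libraries, 12 in all. The libraries were named here WT_mock, WT_ABA, osfkbp20-1b_mock and osfkbp20-1b_ABA, each numbered 1 to 3. Reads on annotated exons and introns totalled 12842345 to 21176117 per library, and introns took 5.57% to 8.86% of them. The files listed 197136 exons and 152469 introns of 44667 transcripts at 37857 loci of the IRGSP-1.0 genome. The series asks how ABA changes splicing, with intron retention as the measured form, and whether the mutant differs. Every p-value below for a single gene or intron measured the spread between these samples only, because the labels do not state that replicates were separate plants. Camera p-values compared the genes of a list with other genes, and Fisher p-values were taken across genes.

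OsFKBP20-1b (Os05g0458100, annotated as similar to FK506-binding protein 4; chromosome 5, 22492473 to 22494991, minus strand) was expressed in all 12 libraries. Its normalised exon reads averaged 322 ± 17.0 in WT_mock and 346 ± 60.4 in WT_ABA (SD, n = 3). In the mutant they averaged 275 ± 58.8 after mock and 357 ± 40.6 after ABA. The libraries read 304, 338 and 324 in WT_mock, 416, 315 and 308 in WT_ABA, 283, 213 and 330 in osfkbp20-1b_mock, and 315, 362 and 396 in osfkbp20-1b_ABA. The log2 difference of mutant from wild type was −0.24 after mock (limma adjusted p = 1) and 0.05 after ABA (limma adjusted p = 0.963). ABA changed the gene by 0.07 in wild type (limma adjusted p = 0.764) and by 0.39 in the mutant (limma adjusted p = 0.149). The column headings abbreviate the mutant as KO, but the labels do not say what kind of change it carries or where in the gene it lies. These reads showed no clear loss of the transcript in the mutant and so did not check the labels. Its introns carried 1 to 18 reads per library.

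**Figure D1:**
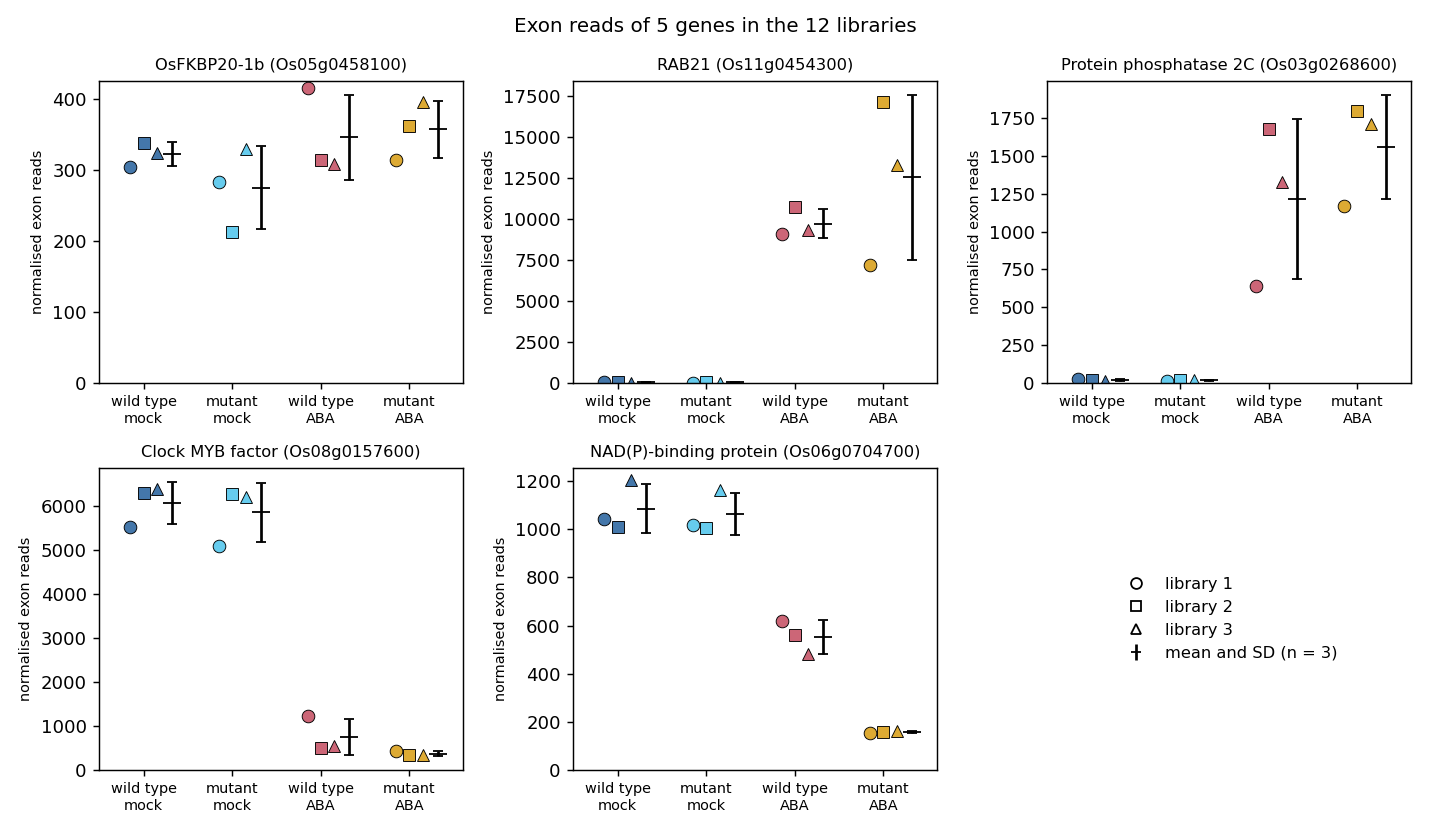
Normalised exon reads (vertical axes, linear from 0) of OsFKBP20-1b, the dehydrin RAB21, a type 2C protein phosphatase, a clock MYB factor and Os06g0704700 in the 4 groups, where points are libraries and bars are mean ± SD (n = 3). RAB21 averaged 16.5 ± 10.7 in WT_mock and 9714 ± 891 in WT_ABA, while OsFKBP20-1b stayed between 213 and 416 in every library.

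The first comparison asked which transcripts ABA changed in wild type. Dehydrin and late embryogenesis abundant (LEA) genes, which protect drying cells, rose most. RAB21 (Os11g0454300) rose from 14.5 ± 9.35 to 8387 ± 794 normalised exon reads (SD, n = 3; log2 9.30, SE 0.42; limma adjusted p = 2.39e-06). Dehydrin DHN1 (Os11g0451700) rose by 9.15 (SE 0.49; adjusted p = 5.07e-06), RAB16D (Os11g0453900) by 8.92 and the LEA gene Os05g0542500 by 8.63. The dehydrin Os11g0454200 rose by 8.36, a 1-Cys peroxiredoxin (Os07g0638300) by 8.28, a TspO-related gene (Os05g0151200) by 8.12 and the group 1 LEA gene Os08g0327700 by 7.75. Of 25 LEA and dehydrin genes tested, 23 rose and 0 fell, with 24 rising when adjusted over the list alone, and the median log2 change was 5.94. The camera test with preset correlation put the list up (adjusted p = 2e-22, or adjusted p = 0.0629 with an estimated correlation). LEA medians were at most 12.4 reads in the 6 mock libraries and 633 to 848 in the 3 WT_ABA libraries.

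Several genes of ABA signalling and turnover rose with them. The type 2C protein phosphatase Os03g0268600 rose from 14.4 ± 4.84 to 1049 ± 460 reads (log2 6.04, SE 0.38; adjusted p = 1.12e-05), Os01g0846300 by 2.91 and Os01g0656200 by 4.10. A bZIP activator (Os06g0211200) rose by 2.03 (SE 0.16; adjusted p = 3.59e-05). ABA 8'-hydroxylase (Os02g0703600), which breaks ABA down, rose by 2.05 (adjusted p = 3.87e-05), and zeaxanthin epoxidase (Os04g0448900) by 1.02 (adjusted p = 0.00103). In the ABA signalling list, which partial word matches made include NAS1 and NAS3, 15 of 29 genes rose and 4 fell, or 17 and 6 adjusted over the list alone (camera up, adjusted p = 0.000287, or adjusted p = 0.203 with an estimated correlation). With whole-word matching 12 of 15 rose and 1 fell, or 13 and 2 over the list alone (adjusted p = 1.16e-06, or adjusted p = 0.106 with an estimated correlation). Both ABA metabolism genes rose, also over the list alone.

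Some splicing factor genes rose after ABA in wild type. SCL30a (Os07g0633200), an SC35-like factor, rose from 135 ± 16.6 to 472 ± 119 reads (log2 1.77, SE 0.21; adjusted p = 0.000448), and SF2 (Os01g0316600) rose by 1.97 (SE 0.15; adjusted p = 3.05e-05). SCL30 (Os12g0572400) rose by 1.14 and the SYF2 family gene Os06g0711600 by 0.69. Of 22 SR protein genes 6 rose and 1 fell, the same over the list alone (camera up, adjusted p = 0.00633, or adjusted p = 0.355 with an estimated correlation). Whole-word matching left 17, of which 4 rose and 0 fell, the same over the list alone (adjusted p = 0.0102, or adjusted p = 0.16 with an estimated correlation). Of 45 spliceosome genes 11 rose and 1 fell, or 15 and 1 over the list alone (camera up, adjusted p = 0.00236, or adjusted p = 0.355 with an estimated correlation). Among 45 FKBP and cyclophilin genes, relatives of OsFKBP20-1b, 3 rose and 5 fell, or 1 and 4 over the list alone. The cyclophilin Os08g0382400 fell by 0.74 (adjusted p = 0.00354), a call lost when all 12 libraries were fitted together.

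Clock and root genes also moved in wild type. The clock MYB factor Os08g0157600 fell from 5297 ± 424 to 642 ± 350 reads (log2 −3.17, SE 0.30; adjusted p = 0.000123). The ZGT clock gene (Os05g0494600) rose by 4.51, the GIGANTEA orthologue (Os01g0182600) by 1.73 and a pseudo-response regulator (Os09g0532400) by 1.75. Of 19 clock genes 7 rose and 2 fell, the same over the list alone, and with whole-word matching 7 of 16 rose and 1 fell, also the same (camera up, adjusted p = 0.0223, or adjusted p = 0.16 with an estimated correlation). Root markers, in a list chosen after the data were seen, fell. The silicon transporter Lsi1 (Os02g0745100) fell by 1.43 (SE 0.18; adjusted p = 0.000535) and RCc2 (Os10g0551800) by 3.85. Of 8 root markers 7 fell and 0 rose, the same over the list alone (camera down, adjusted p = 0.000351, or adjusted p = 0.114 with an estimated correlation). The peroxidase Os05g0134800 fell from 203 ± 33.2 to 2.85 ± 0.387 reads (log2 −5.72; adjusted p = 3.29e-06), the peroxidase Os07g0677300 fell by 4.73, a leucine-rich repeat gene (Os03g0145102) by 4.49 and a papain-like protease gene (Os01g0347500) by 4.42.

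Some iron acquisition genes fell in wild type with a wide spread between libraries. Nicotianamine synthase 1 (NAS1, Os03g0307300) fell by 5.76 (SE 1.70; adjusted p = 0.031), NAS2 (Os03g0307200) by 5.25, a nicotianamine aminotransferase-like gene (Os02g0306401) by 5.13 and a major facilitator gene (Os11g0134900) by 6.18. NAS1 read 11545 to 15883 in WT_mock but 8455, 77.6 and 24.8 in WT_ABA_1 to WT_ABA_3. These 4 calls were lost under edgeR and when WT_mock_1, WT_mock_3 or WT_ABA_2 was left out, and all but Os11g0134900 also without WT_mock_2 or WT_ABA_3, with highest adjusted p of 0.123 to 0.274 under limma or edgeR. The iron list, chosen after the data were seen, had 14 genes, of which 2 rose and 4 fell, or 4 and 7 over the list alone. Its median was −0.60, and neither form of camera called it.

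The other lists showed mixed changes after ABA in wild type. Heat shock protein 70 (Os03g0277300) rose from 68.6 ± 34.2 to 566 ± 195 reads (log2 3.11; adjusted p = 0.000492). Of 171 heat shock and chaperone genes 32 rose and 11 fell, or 28 and 11 over the list alone. The photosystem II 10 kDa gene Os07g0147550 rose by 5.68 while the chlorophyll-binding protein gene Os01g0720500 fell by 1.44 (adjusted p = 0.00163), a call lost when all 12 libraries were fitted together. Of 59 photosynthesis genes 4 rose and 6 fell, or 2 and 4 over the list alone. The ribosomal L18A gene Os05g0564800 rose by 0.90, and of 292 ribosomal genes 18 rose and 10 fell, or 4 and 3 over the list alone. Their median was 0.01 and their mean −0.01, and camera placed them up without a call. The heat shock factor Os02g0232000 rose by 2.65 and the NAC gene Os12g0123700 by 3.31 (adjusted p = 5.73e-05). Of 90 stress transcription factors 21 rose and 12 fell, or 22 and 15 over the list alone. The single nonsense-mediated decay gene did not pass (log2 0.30), also over the list alone. Of 62 genes of other organs 6 rose and 15 fell, the same over the list alone, with a median of 0.18, a mean of −0.25 and camera down without a call. The medians of heat shock, photosynthesis, ribosomal, stress factor, clock and other-organ genes were small here and turned negative under the authors' scaling (those of photosynthesis, ribosomal and stress factor genes also under upper-quartile scaling), while those of LEA, ABA signalling, SR, spliceosome and root genes kept their sign.

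In all, 6625 of 22016 tested genes changed in exon reads after ABA in wild type (3137 higher, 3488 lower; limma). Unadjusted p was below 0.05 for 9131 genes, and edgeR called 6657 and DESeq2 6828. Under the authors' scaling 1823 were higher and 5023 lower, where the median gene moved by −0.22 relative to the scaling used here. The count was 4316 without WT_mock_1 and 4244 without WT_mock_2.

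Intron reads in wild type changed mostly at genes whose exon reads changed. Intron 1 of the LEA-18 gene Os09g0482300 rose from 3.28 ± 2.19 to 566 ± 62.4 normalised reads (log2 7.19, SE 0.34; adjusted p = 4.89e-09), and its near-identical copy Os09g0482550 rose by 7.09. Intron 2 of a mitochondrial import gene (Os03g0305600) rose by 6.42, intron 1 of a glycoside hydrolase gene (Os11g0700900) by 4.87 and intron 1 of the phosphatase gene Os01g0656200 by 3.35. Intron 1 of a release factor-like gene (Os05g0373900) rose at least 20.6-fold from the floor. Intron 9 of the clock MYB gene Os08g0157600 fell from 377 ± 9.75 to 16.1 ± 5.69 (log2 −4.51, SE 0.26; adjusted p = 2.79e-08). Introns of a P450 gene (Os03g0658800) and a leucine-rich repeat gene (Os03g0145102) fell by 3.82 and 4.02. Introns of a major facilitator gene (Os11g0134900) and a thionin-like gene (Os07g0431160) fell by 4.16 and 3.93, calls lost under DESeq2. Intron 7 of SF2 rose by 1.69 (adjusted p = 0.000878) and intron 1 of the cyclophilin gene Os08g0382400 fell by 1.18 (adjusted p = 0.00938).

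Summed over each gene's introns, LEA genes rose in 10 of 11 and fell in 0, the same over the list alone (camera up, adjusted p = 8.39e-20, or adjusted p = 0.0399 with an estimated correlation). ABA signalling genes rose in 11 of 23 and fell in 1, or 12 and 1 over the list alone (adjusted p = 3.69e-07, or adjusted p = 0.0706 with an estimated correlation). Photosynthesis genes fell in 8 of 34 and rose in 1, or 12 and 1 over the list alone (camera down, adjusted p = 0.00114, or adjusted p = 0.347 with an estimated correlation). Spliceosome genes rose in 1 of 35 (camera up, adjusted p = 0.02, or adjusted p = 0.221 with an estimated correlation). Clock genes rose in 3 of 15 and fell in 1, and stress transcription factors rose in 9 of 50 and fell in 4.

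Of 20766 tested introns 1927 changed after ABA in wild type (956 higher, 971 lower; limma), in 1221 genes. Unadjusted p was below 0.05 for 4756, and edgeR called 2092 and DESeq2 1254. Under the authors' scaling 603 were higher and 985 lower, with the median intron moved by −0.14. Of the 1927, 1705 (88.5%) lay in genes whose exon reads were called in the same direction and 0 in the opposite direction, and 651 (33.8%) overlapped an annotated exon. Across introns, which are not independent replicates, the change correlated with the exon change at 0.933. As a ratio to exon reads, 2 of 17358 introns changed, both lower (limma, 1040 with unadjusted p below 0.05, edgeR 4 and DESeq2 10). The intron count was 1010, 1050 and 1191 without WT_mock_1, WT_mock_2 or WT_mock_3, 1210 without WT_ABA_2 and 3094 without WT_ABA_1.

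The same ABA comparison in the mutant asked whether the response was present there. Dehydrins again rose most. DHN1 rose from 7.55 ± 1.34 to 26812 ± 3992 reads (SD, n = 3; log2 11.62, SE 0.17; limma adjusted p = 3.84e-09), RAB21 by 10.14 (SE 0.34; adjusted p = 2.72e-07) and RAB16D by 9.59. The dehydrin Os11g0454200 rose by 9.94, the LEA gene Os05g0542500 by 9.91 (adjusted p = 1.61e-07), the TspO-related gene by 9.33 and the undescribed Os10g0505900 by 9.22. An embryo-specific gene (Os05g0569500) rose at least 317-fold from the floor. Of 28 LEA genes 25 rose and 0 fell, the same over the list alone, with a median of 6.65, or 6.63 with genes at the floor set to their bound (camera up, adjusted p = 1.81e-23, or adjusted p = 0.14 with an estimated correlation). LEA medians in the 3 osfkbp20-1b_ABA libraries were 940 to 1235 reads.

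Some ABA signalling and splicing factor genes rose in the mutant as well. The phosphatase Os03g0268600 rose from 17.0 ± 2.83 to 1764 ± 388 reads (log2 6.60, SE 0.22; adjusted p = 2.64e-07), Os09g0325700 by 5.52 and Os01g0846300 by 3.25. ABA 8'-hydroxylase rose by 1.73 (adjusted p = 0.000379), and zeaxanthin epoxidase by 0.55, a call lost without osfkbp20-1b_mock_2 (limma adjusted p = 0.0522). Of 31 ABA signalling genes 17 rose and 3 fell, or 18 and 3 over the list alone (camera up, adjusted p = 9.43e-06, or adjusted p = 0.307 with an estimated correlation). With whole-word matching 12 of 17 rose and 0 fell, or 13 and 0 over the list alone (adjusted p = 1.49e-07, or adjusted p = 0.106 with an estimated correlation). SCL30a rose from 190 ± 41.8 to 626 ± 34.5 (log2 1.74; adjusted p = 0.000213), SCL30 by 0.83 and SF2 by 1.24. Of 22 SR genes 7 rose and 1 fell, the same over the list alone (camera up, adjusted p = 0.0342, or adjusted p = 0.611 with an estimated correlation), and of the whole-word 17, 6 rose and 0 fell (adjusted p = 0.0288, or adjusted p = 0.453 with an estimated correlation). Of 45 spliceosome genes 13 rose and 0 fell, the same over the list alone (camera up, adjusted p = 0.000287, or adjusted p = 0.355 with an estimated correlation). FKBP and cyclophilin genes rose in 8 of 46 and fell in 8, the same over the list alone, with the cyclophilin Os08g0382400 down by 1.81 (adjusted p = 0.00448).

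Single peroxidase, iron, clock and root genes changed in the mutant. The peroxidase Os05g0134800 fell from 289 ± 71.1 to 4.11 ± 1.95 reads (log2 −5.86; adjusted p = 6.64e-06), the major facilitator gene Os11g0134900 by 6.18, while NAS1 fell by 5.23 (SE 1.23; adjusted p = 0.0118) and NAS2 by 4.93. A leucine-rich repeat gene (Os03g0145102) fell by 5.19, a retrovirus-like gene (Os01g0347600) by 4.67, a dirigent gene (Os10g0335000) by 4.61 and a beta-ring hydroxylase gene (Os10g0533500) by 4.54. The clock MYB factor fell from 6617 ± 753 to 413 ± 65.0 (log2 −4.00, SE 0.16; adjusted p = 5.67e-07), ZGT rose by 4.78 and GIGANTEA by 2.00. Of 19 clock genes 8 rose and 2 fell, or 8 and 3 over the list alone, and of the whole-word 16, 8 rose and 2 fell (camera up, adjusted p = 0.0426, or adjusted p = 0.453 with an estimated correlation). Lsi1 fell by 1.57, and of 8 root markers 6 fell and 0 rose, the same over the list alone (camera down, adjusted p = 0.000351, or adjusted p = 0.425 with an estimated correlation). Of 14 iron genes 2 rose and 5 fell, or 2 and 6 over the list alone, without a camera call. NAS1 read 10049 to 13576 in osfkbp20-1b_mock but 2662, 31.7 and 328 in osfkbp20-1b_ABA_1 to osfkbp20-1b_ABA_3.

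Some photosynthesis genes fell and some ribosomal genes rose in the mutant. The photosystem II gene PsbX (Os03g0343900) fell by 1.53 (adjusted p = 0.00691), and of 58 photosynthesis genes 19 fell and 3 rose, or 24 and 3 over the list alone (camera down, adjusted p = 0.000287, or adjusted p = 0.842 with an estimated correlation). The photosynthesis median was 827 in osfkbp20-1b_ABA_1 and 2512 to 4199 in the other 5 ABA libraries. The ribosomal L10 gene Os05g0169100 rose by 1.26, and of 295 ribosomal genes 59 rose and 12 fell, or 30 and 5 over the list alone (camera up, adjusted p = 0.000102, or adjusted p = 0.842 with an estimated correlation). Heat shock protein 70 rose from 77.2 ± 12.3 to 1228 ± 175, and of 175 heat shock genes 34 rose and 16 fell, or 32 and 14 over the list alone. The heat shock factor Os01g0733200 rose by 4.05, and of 96 stress transcription factors 25 rose and 10 fell, or 26 and 12 over the list alone, with a median of −0.07, a mean of 0.23 and camera up without a call. Both ABA metabolism genes rose, and the nonsense-mediated decay gene did not pass (log2 0.06). Genes of other organs fell in 12 of 68 and rose in 5, the same over the list alone (median −1.65; camera down, adjusted p = 0.00873, or adjusted p = 0.802 with an estimated correlation). Among these, 37 glutelin and prolamin genes, which store protein in the seed, had medians of 592 and 487 in osfkbp20-1b_mock_1 and osfkbp20-1b_mock_2.

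In the mutant 7298 of 23037 tested genes changed in exon reads (3621 higher, 3677 lower; limma), with unadjusted p below 0.05 for 9944, and edgeR called 7264 and DESeq2 7583. The count was 4608 without osfkbp20-1b_mock_2. Intron 1 of Os09g0482300 rose at least 343-fold from the floor, to 1029 ± 247 reads (SE of log2 0.28; adjusted p = 2.62e-12). The mitochondrial import gene's intron 2 rose by 6.93, intron 1 of a phosphatidylethanolamine-binding gene (Os05g0468800) by 6.46, and intron 1 of DHN1 at least 46.6-fold. Intron 1 of the phosphatase gene Os01g0656200 rose by 4.32 and intron 9 of the clock MYB gene fell by 5.12 (SE 0.28; adjusted p = 1.13e-08). Introns of a NAC gene (Os08g0200600) and a leucine-rich repeat gene (Os03g0145102) fell by 4.03 and 4.31. Intron 7 of SF2 rose by 1.29, a call lost without osfkbp20-1b_mock_1, osfkbp20-1b_mock_3, osfkbp20-1b_ABA_2 or osfkbp20-1b_ABA_3 (highest limma adjusted p = 0.079).

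Summed over introns, mutant LEA genes rose in 11 of 12 and fell in 0 (camera up, adjusted p = 3.46e-20, or adjusted p = 0.196 with an estimated correlation). ABA signalling genes rose in 15 of 24, or 17 over the list alone (adjusted p = 4.13e-11, or adjusted p = 0.0405 with an estimated correlation). Photosynthesis genes fell in 17 of 35 and rose in 2, or 26 and 2 over the list alone (camera down, adjusted p = 6.36e-10, or adjusted p = 0.474 with an estimated correlation). Ribosomal genes rose in 10 of 219 and fell in 2 (camera up, adjusted p = 0.000378, or adjusted p = 0.618 with an estimated correlation). SR genes rose in 2 of 18 (adjusted p = 0.02, or adjusted p = 0.438 with an estimated correlation) and spliceosome genes in 4 of 38 (adjusted p = 0.033, or adjusted p = 0.221 with an estimated correlation). Of all 54 intron-sum tests of lists, 19 passed with preset correlation, and with an estimated correlation only LEA genes in wild type and ABA signalling genes in the mutant did. Of 55 exon tests 20 passed with preset correlation and 0 with an estimated one. The rotation test fry, which asks whether a list moves in 1 direction at all, called 7 of the intron-sum and 14 of the exon tests.

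Of 22923 tested introns 1981 changed after ABA in the mutant (918 higher, 1063 lower; limma), in 1224 genes. Unadjusted p was below 0.05 for 4887, and edgeR called 2085 and DESeq2 1502. Of the 1981, 1787 (90.2%) lay in genes whose exon reads were called in the same direction, 0 in the opposite direction, and 617 (31.1%) overlapped an annotated exon. The ratio to exon reads changed for 8 of 21680 introns, all lower (limma, 941 with unadjusted p below 0.05, edgeR 0 and DESeq2 11). Among them were intron 1 of RAB21 (ratio log2 −4.46; adjusted p = 0.0019) and of DHN1 (ratio log2 −5.11; adjusted p = 0.00265), genes whose exon reads rose by 10.14 and 11.62. In osfkbp20-1b_mock RAB21 had 7.08 to 14.9 normalised exon reads and DHN1 5.31 to 7.43, while every feature held at least 1 read. The floor can hold up the mock ratio, so these falls have no exact size and do not show less retention. The intron count was 1306, 1033 and 1320 without osfkbp20-1b_mock_1, osfkbp20-1b_mock_2 or osfkbp20-1b_mock_3, and 1261 and 1230 without osfkbp20-1b_ABA_2 or osfkbp20-1b_ABA_3.

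The ABA responses of the genotypes, which share no libraries, overlapped. LEA, dehydrin, phosphatase and clock genes named above moved the same way in both. Among 21894 genes tested in both, 2219 rose in both, of 3124 in wild type and 3502 in the mutant, where 500 were expected by chance. Another 2429 fell in both, of 3459 and 3584, where 566 were expected, and 6 went opposite ways. Among 18787 introns 503 rose in both, of 871 and 760 (35.2 expected), and 487 fell in both, of 914 and 974 (47.4 expected). Of introns called in either genotype, 2441 of 2529 (96.5%) had the same sign. No intron called relative to exon reads was shared.

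The mock comparison of genotypes asked what the mutation changed without ABA, and few genes passed. Os03g0115800, an undescribed gene, rose from 2.38 ± 0.996 to 1094 ± 160 reads in the mutant (SD, n = 3; log2 8.38, SE 0.27; limma adjusted p = 5.86e-08), and Os03g0299700 rose by 6.73 (adjusted p = 4.83e-07). An F-box gene (Os10g0567900) rose by 3.73 (adjusted p = 0.00114), an EGG APPARATUS-1-like gene (Os07g0605350) by 3.90 and a glycoside hydrolase gene (Os04g0474300) by 1.60 (173 ± 6.52 to 530 ± 78.1; adjusted p = 0.00036). A long noncoding RNA (Os01g0356951) rose at least 9.60-fold from the floor. A P450 gene (Os06g0294600) fell by 2.55 (adjusted p = 0.00114) and a C2-domain gene (Os01g0242600) by 1.11 (adjusted p = 0.000885). A thionin-like gene (Os07g0430501) fell by 2.20 and a NUDIX hydrolase gene (Os11g0531700) by 1.59, calls lost when all 12 libraries were fitted together. An integrin-like gene (Os07g0580700) rose by 2.89, a nitrite reductase-like gene (Os02g0765900) by 2.14 and a laccase-like gene (Os11g0641800) by 1.69, and a beta-amylase gene (Os07g0543300) fell by 1.09. The integrin-like call was lost without WT_mock_2, WT_mock_3 or osfkbp20-1b_mock_1 (highest limma adjusted p = 0.161), and the nitrite reductase-like call without WT_mock_1, WT_mock_2 or osfkbp20-1b_mock_1. The laccase-like call was lost without WT_mock_1, WT_mock_2 or osfkbp20-1b_mock_2, and the beta-amylase call without WT_mock_1, osfkbp20-1b_mock_1 or osfkbp20-1b_mock_2 (highest limma adjusted p of these 3 calls from 0.31 to 1). The undescribed Os10g0159300 fell by 2.25. The thionin-like Os07g0431160 fell by 1.68, a call lost without WT_mock_2 or osfkbp20-1b_mock_2, and Os07g0432333 fell from 1317 ± 365 to 469 ± 152, a call lost on leaving out any 1 library except osfkbp20-1b_mock_3. Both calls were also lost when all 12 libraries were fitted together (limma adjusted p = 1 for both).

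Of 22685 genes 41 differed between genotypes after mock (33 higher, 8 lower in the mutant; limma), with unadjusted p below 0.05 for 1029, and edgeR called 42 and DESeq2 87. The count was 277 without osfkbp20-1b_mock_3, and 91 (47 higher, 44 lower) with the heading number as a model term. Without osfkbp20-1b_mock_1, osfkbp20-1b_mock_2 and WT_ABA_1 it was 58, with 23 higher and 35 lower. No LEA, ABA signalling, SR, spliceosome, FKBP or other listed gene passed. Over the list alone 1 gene of the ABA signalling list (0 with whole-word matching), 1 LEA, 1 other-organ and 1 iron gene were lower. Genes of other organs stood higher in the mutant by camera (median 0.78; adjusted p = 0.0055, or adjusted p = 0.802 with an estimated correlation) and iron genes lower (adjusted p = 0.0357, or adjusted p = 0.453 with an estimated correlation). The glutelin and prolamin median was 592, 487 and 531 in osfkbp20-1b_mock_1, osfkbp20-1b_mock_2 and WT_ABA_1, and 18.2 to 143 in the other 9 libraries. Intron sums of ribosomal genes stood lower (adjusted p = 0.0132, or adjusted p = 0.7 with an estimated correlation).

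Intron reads differed at 7 of 23451 introns after mock (4 higher, 3 lower; limma), with unadjusted p below 0.05 for 810, and edgeR called 10 and DESeq2 5. Intron 1 of the non-protein-coding transcript Os04g0587451 rose from 2.88 ± 0.932 to 146 ± 15.3 reads in the mutant (log2 5.27, SE 0.30; adjusted p = 1.08e-12), while its exon change was 1.04 (adjusted p = 1). Intron 2 of the thionin-like Os07g0431160 fell by 1.84 (adjusted p = 0.000153), a call lost when all 12 libraries were fitted together. Intron 3 of Os08g0410900 rose at least 8.65-fold, a call lost without any 1 of the mutant mock libraries (highest limma adjusted p = 1). Of the 7 introns 6 overlapped an annotated exon, that of Os04g0587451 among them. For the ratio to exon reads 0 of 21113 introns differed in limma, edgeR and DESeq2, with unadjusted p below 0.05 for 568. The limma test recovered 56.7% of simulated 4-fold and 2.08% of simulated 2-fold ratio changes here, so smaller changes could be missed. The intron count was 2 without osfkbp20-1b_mock_2, 34 without osfkbp20-1b_mock_3 and 24 (13 higher, 11 lower) with the heading number as a model term.

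The comparison of genotypes after ABA asked the same under the hormone. Os03g0115800 rose from 1.86 ± 1.19 to 792 ± 165 reads in the mutant (SD, n = 3; log2 8.17, SE 0.34; limma adjusted p = 8.41e-05), Os03g0299700 by 7.15, the F-box gene by 3.46, the EGG APPARATUS-1-like gene by 3.30 and the glycoside hydrolase gene Os04g0474300 by 1.43. Isoamylase 1 (Os08g0520900), a starch-debranching enzyme, rose from 168 ± 7.48 to 401 ± 29.4 (adjusted p = 0.0344). A wall-associated kinase gene (Os10g0180800) fell by 2.19 (adjusted p = 0.0446), the NAD(P)-binding gene Os06g0704700 by 1.81 (adjusted p = 0.011) and a receptor-like kinase gene (Os05g0256100) by 1.32 (adjusted p = 0.0236). Of these only Os03g0115800 and Os03g0299700 kept their call when each library was left out, and the others reached highest limma adjusted p of 0.131 to 0.298. All 7 others lost it without WT_ABA_2, osfkbp20-1b_ABA_2 or osfkbp20-1b_ABA_3, and all but Os06g0704700 without osfkbp20-1b_ABA_1. Without WT_ABA_3 it was lost for all but the F-box gene and Os06g0704700, and without WT_ABA_1 for isoamylase 1 and the wall-associated kinase gene.

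Of 21833 genes 23 differed after ABA (20 higher, 3 lower; limma), with unadjusted p below 0.05 for 2020, and edgeR called 22. DESeq2 called 244 (104 higher, 140 lower), and 262 were called with all 12 libraries in 1 fit (114 higher, 148 lower). Without WT_ABA_1 and osfkbp20-1b_ABA_1 there were 669 (296 higher, 373 lower), so the balance of higher and lower calls depended on the fit. The count was 28 without WT_ABA_1, 6 without WT_ABA_2, 12 without WT_ABA_3, and 6, 3 and 4 without osfkbp20-1b_ABA_1, osfkbp20-1b_ABA_2 or osfkbp20-1b_ABA_3. Under the authors' scaling the median gene moved by 0.30. No gene of any list passed. Over the list alone 5 photosynthesis and 3 heat shock genes were lower and 1 FKBP gene higher. Photosynthesis genes stood lower by camera (median −0.89; adjusted p = 2.2e-16, or adjusted p = 0.495 with an estimated correlation), with the low values of osfkbp20-1b_ABA_1 given above. LEA genes stood higher (median 0.37; adjusted p = 0.000347, or adjusted p = 0.495 with an estimated correlation), as did ribosomal genes (median 0.22; adjusted p = 5.7e-08, or adjusted p = 0.79 with an estimated correlation) and ABA signalling genes (median 0.09; adjusted p = 0.0327, or adjusted p = 0.355 with an estimated correlation; whole-word adjusted p = 0.00419, or adjusted p = 0.145 with an estimated correlation). Intron sums of photosynthesis genes stood lower (adjusted p = 3.95e-11, or adjusted p = 0.38 with an estimated correlation), and those of ribosomal (adjusted p = 2.47e-08, or adjusted p = 0.221 with an estimated correlation) and ABA signalling genes (adjusted p = 0.0206, or adjusted p = 0.221 with an estimated correlation) higher.

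After ABA 1 of 18077 introns differed (limma, 1049 with unadjusted p below 0.05, edgeR 1 and DESeq2 7). It was again intron 1 of Os04g0587451, which rose from 1.85 ± 1.35 to 105 ± 22.3 reads in the mutant (log2 5.30, SE 0.39; adjusted p = 4.99e-06). This intron overlaps an annotated exon, so its reads can be exon reads, and it was not tested relative to exon reads. Relative to exon reads 0 of 17680 introns differed in limma, edgeR and DESeq2, with unadjusted p below 0.05 for 537. The limma test recovered 9.32% of simulated 4-fold ratio changes here, so these 0 calls do not show equal ratios. The intron count was 46 without WT_ABA_1 and 10 without osfkbp20-1b_ABA_3. The genotype comparisons, which share no libraries, had 18 genes higher in common, of 29 after mock and 20 after ABA among 21134 tested in both, where 0.0274 were expected by chance (Fisher p = 5.99e-53 across genes, which are not independent replicates), and 0 lower in common of 8 and 3. Os03g0115800, Os03g0299700 and the glycoside hydrolase gene Os04g0474300 were among the 18. The Os04g0587451 intron was the 1 intron in common, of 3 and 1 called among 16051.

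The interaction asked whether the ABA response itself differed between genotypes. The NAD(P)-binding gene Os06g0704700 (chromosome 6, 29762530 to 29766745) fell further in the mutant. It averaged 1087 ± 103 reads in WT_mock and 553 ± 70.6 in WT_ABA (SD, n = 3), and 1064 ± 88.8 in osfkbp20-1b_mock and 157 ± 3.03 in osfkbp20-1b_ABA. The difference in log2 response was −1.78 (SE 0.18; limma adjusted p = 0.00545). It was the only 1 of 22620 genes called by limma, with unadjusted p below 0.05 for 1791, and edgeR called 1 and DESeq2 115. Under the authors' scaling the median gene moved by 0.22. The gene count was 31 without osfkbp20-1b_ABA_3, 11 without WT_ABA_1 and 2 without WT_mock_3, osfkbp20-1b_mock_3, WT_ABA_2 or WT_ABA_3.

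The interaction of 29385 introns gave 0 calls in limma, edgeR and DESeq2, with unadjusted p below 0.05 for 1406 and a smallest limma adjusted p of 0.725. Leaving out WT_ABA_1 gave 8, osfkbp20-1b_ABA_3 4, and osfkbp20-1b_mock_3 or osfkbp20-1b_ABA_2 1. Relative to exon reads 0 of 19362 introns were called by the same 3 tools, with unadjusted p below 0.05 for 512. The limma test recovered 0% of simulated 4-fold ratio changes here, so these 0 calls do not show that the ratios responded alike. LEA genes responded more in the mutant by camera (median 0.77; adjusted p = 2.95e-07, or adjusted p = 0.14 with an estimated correlation). LEA medians after mock were 5.84 to 12.4 reads in WT_mock and at most 6.19 in osfkbp20-1b_mock, near the floor. After ABA they were 633 to 848 in WT_ABA and 940 to 1235 in osfkbp20-1b_ABA. The LEA difference in response therefore has no exact size and does not by itself show a stronger ABA effect in the mutant. Camera also placed the mutant response higher for ribosomal genes (median 0.27; adjusted p = 2.37e-08, or adjusted p = 0.724 with an estimated correlation) and ABA signalling genes (median 0.21; adjusted p = 0.0327, or adjusted p = 0.355 with an estimated correlation). Photosynthesis genes responded downward (median −1.03; adjusted p = 1.62e-15, or adjusted p = 0.408 with an estimated correlation). Their median was 827 reads in osfkbp20-1b_ABA_1 against 2554 and 3110 in osfkbp20-1b_ABA_2 and osfkbp20-1b_ABA_3. Over the list alone 2 LEA genes were higher, and 1 ABA metabolism and 3 heat shock genes lower. Intron sums gave LEA (adjusted p = 0.00294, or adjusted p = 0.353 with an estimated correlation), ribosomal (adjusted p = 1.14e-09, or adjusted p = 0.221 with an estimated correlation), ABA signalling (adjusted p = 0.0144, or adjusted p = 0.196 with an estimated correlation) and other-organ genes (adjusted p = 0.0403, or adjusted p = 0.386 with an estimated correlation) up, and photosynthesis genes (adjusted p = 1.14e-09, or adjusted p = 0.353 with an estimated correlation) down.

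The authors' own tables listed introns whose ratio to flanking exons differed. They listed 517 after ABA in wild type (216 higher, 301 lower) and 454 in the mutant (61 higher, 393 lower). Between genotypes they listed 203 after mock (100 higher, 103 lower in the mutant) and 331 after ABA (41 higher, 290 lower). Counting each position once left 396, 354, 155 and 240 introns. Of those testable here relative to exon reads, 1 of 360, 6 of 338, 0 of 148 and 0 of 220 passed limma, and 310, 283, 116 and 175 had unadjusted p below 0.05. That test recovered 0% to 2.08% of simulated 2-fold ratio changes, so not passing does not show that a listed intron was unchanged. By intron reads alone 88 of 381, 116 of 352, 1 of 154 and 0 of 228 passed.

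**Figure D2:**
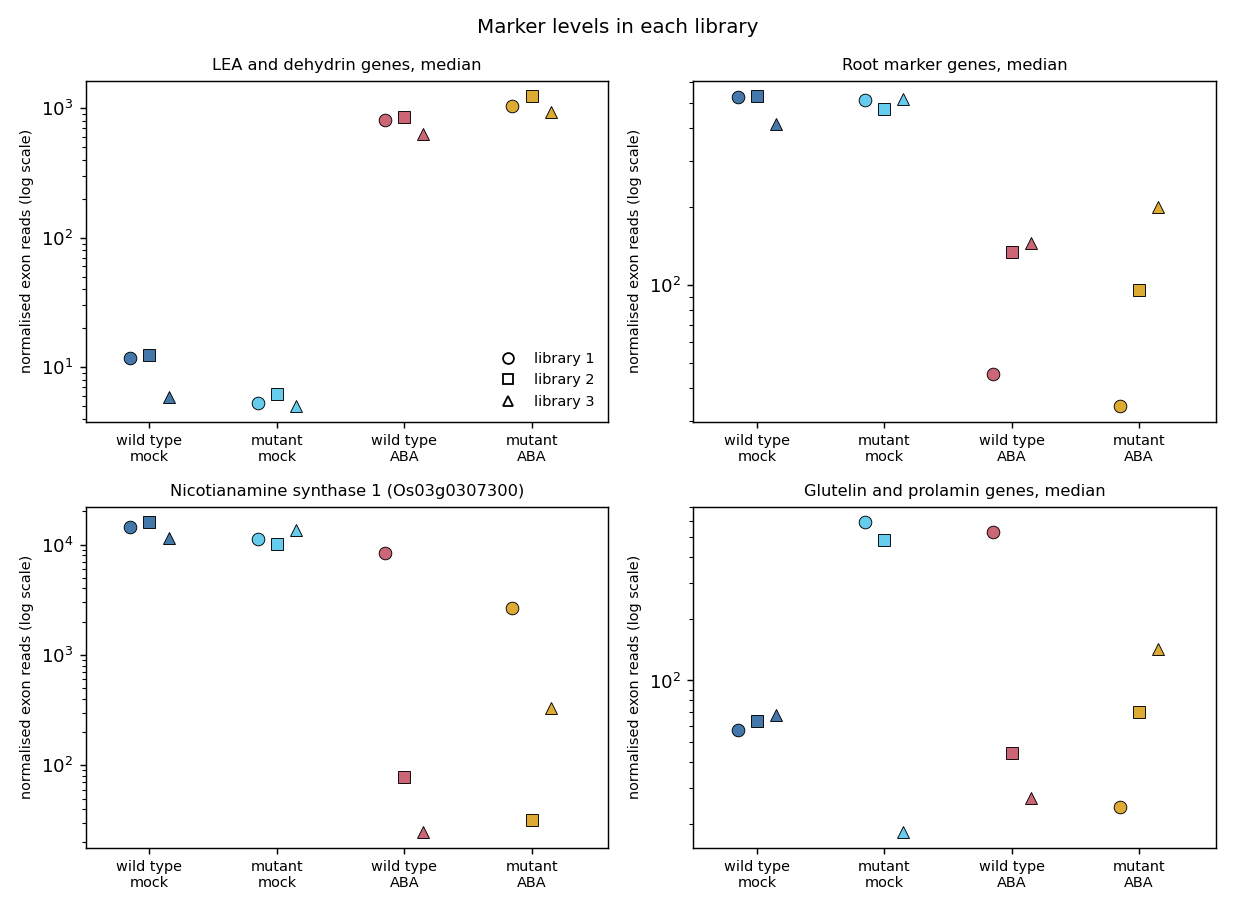
Normalised exon reads per library (vertical axes, logarithmic) as the median of LEA and dehydrin genes, the median of root markers, the NAS1 gene, and the median of glutelin and prolamin genes, with 1 point per library in 4 groups. NAS1 read 8455 in WT_ABA_1 and 2662 in osfkbp20-1b_ABA_1 against 24.8 to 328 in the other ABA libraries, and glutelin and prolamin medians were 592, 487 and 531 in osfkbp20-1b_mock_1, osfkbp20-1b_mock_2 and WT_ABA_1.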

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

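The tests of other splits were planned before the results were seen, and the gene-level interaction was added after the files were seen. The NAD(P)-binding gene Os06g0704700 stood out because its ABA response differed between genotypes in the interaction test. It fell from 1087 ± 103 to 553 ± 70.6 reads in wild type and from 1064 ± 88.8 to 157 ± 3.03 in the mutant (SD, n = 3), a difference of −1.78 on the log2 scale (limma adjusted p = 0.00545). The call held with RLE scaling, edgeR, DESeq2 and a pseudocount of 5, with either filter and without each single library (adjusted p from 1.91e-13 to 0.0454). It did not hold without osfkbp20-1b_mock_1, osfkbp20-1b_mock_2 and WT_ABA_1 together, but that fit left a lone mutant mock library. The gene read 1166 in that library, osfkbp20-1b_mock_3, and 154 to 160 in osfkbp20-1b_ABA. In wild type it read 560 and 480 in WT_ABA_2 and WT_ABA_3. Of 100 drawn splits of the genotype labels within treatments, 13 gave at least 1 gene, the real one included, and the highest other gave 76 against the real 1. Chance was therefore not excluded for the gene count. Labels were redrawn separately after mock and after ABA, so a drawn split could exchange the genotypes in 1 treatment only. A genotype difference shared by both treatments would then give calls. The 76 calls therefore do not point to a structure of the samples other than genotype.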

How the results depend on the processing

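The planned test, edgeR, became an alternative when limma replaced it. Chosen only after results were seen were the pseudocount of 5, the authors' scaling, centred libraries, introns clear of exons, the heading number, removal of named libraries, and every alternative for gene counts. Named items were run under RLE scaling, DESeq2, edgeR, the pseudocount, the filters, all 12 libraries in 1 fit and leaving out each library, and none of those reversed one. Called under all of these were 34 of 48 introns and 60 of 70 genes for ABA in wild type, 32 of 46 and 65 of 66 for ABA in the mutant, 1 of 7 and 26 of 41 for genotype after mock, and 1 of 1 and 3 of 23 for genotype after ABA. RLE, upper-quartile and the authors' scaling, edgeR and the pseudocount, where run, kept total counts of introns by intron reads and of genes within 1.5-fold, but the authors' scaling left 603 introns (of 956) and 1823 genes (of 3137) higher after ABA in wild type. The cause of each change below was not tested, except where fewer features or libraries were used.

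DESeq2 called 1254 wild-type ABA introns, 7 introns and 244 genes for genotype after ABA, 87 genes for genotype after mock, 115 interaction genes and 38 shared genotype genes against 18. Voom called 0 introns for genotype after ABA. Without a filter 15 introns were called after mock and 50 after ABA between genotypes; with at least 20 reads in 3 libraries 1175 wild-type ABA introns and 3 mock genotype introns were left. Fitting all 12 libraries together gave 3 mock genotype introns, and 20 introns and 262 genes after ABA. Counting genes with a changed intron gave 1221 and 1224 for ABA in wild type and mutant. Relative to exon reads the ABA counts were 2 and 8, with a minimum of 20 reads 0 and 3, with a ratio change of 0.1 again 2 and 8, and with libraries centred 20 and 26; both genotype counts were 0 each time (limma). Introns clear of exons numbered 1260 for wild-type ABA, 1 for mock and 0 for ABA genotype. At 2-fold 3679 and 4120 ABA genes passed, and 2561 were shared. With the heading number 24 introns and 91 genes passed after mock. Of 54 list tests camera called 19 with preset and 2 with an estimated correlation, and fry, which asks another question, called 7.

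Without WT_ABA_1 and osfkbp20-1b_ABA_1 there were 3094 wild-type ABA introns (108 relative to exon reads), 35 mutant ABA introns relative to exon reads, 93 introns and 669 genes for genotype after ABA (0 relative to exon reads), 12 introns and 152 genes for the interaction (1 intron relative to exon reads), and 3 shared genotype introns. Without osfkbp20-1b_mock_1, osfkbp20-1b_mock_2 and WT_ABA_1, where the lone mutant mock library was assumed to vary like the other groups, there were 930 introns and 1632 genes for ABA in the mutant, 35 introns (7 higher, 28 lower) and 58 genes (23 higher, 35 lower, against 33 and 8) for genotype after mock, and 9 introns and 0 genes for the interaction.

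Leaving out each library gave 1010 (WT_mock_1) to 3094 (WT_ABA_1) introns and 4244 (WT_mock_2) to 8927 (WT_ABA_1) genes for ABA in wild type, and 1033 (osfkbp20-1b_mock_2) to 2730 (osfkbp20-1b_ABA_1) introns and 4608 (osfkbp20-1b_mock_2) to 8411 (osfkbp20-1b_ABA_1) genes in the mutant. Genotype after mock ran from 2 (osfkbp20-1b_mock_2) to 34 introns and 29 (osfkbp20-1b_mock_2) to 277 genes, both highest without osfkbp20-1b_mock_3. Genotype after ABA ran from 1 to 46 introns (WT_ABA_1) and 3 (osfkbp20-1b_ABA_2) to 28 genes (WT_ABA_1), and the interaction from 0 to 8 introns (WT_ABA_1) and 1 to 31 genes (osfkbp20-1b_ABA_3). The ratio needed mean intron reads of 10 or more, and 21.4% to 30.3% of features, exons included, stood at 1 read.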

Other observations

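Relative to exon reads, introns of ABA-induced LEA genes stood lower after ABA. The LEA list had a median log2 ratio change of −0.44 in wild type (camera adjusted p = 2.31e-06, or adjusted p = 0.266 with an estimated correlation) and −1.48 in the mutant (camera adjusted p = 3.32e-06, or adjusted p = 0.578 with an estimated correlation). Median exon reads of the LEA list were 12.4 at most in the mock libraries, while every feature held at least 1 read. The floor can hold up the mock ratio of these genes. The LEA falls therefore have no exact size and do not show less retention. Photosynthesis introns stood lower in wild type (camera adjusted p = 6.66e-07, or adjusted p = 0.993 with an estimated correlation). Between genotypes after ABA camera placed photosynthesis introns up (adjusted p = 0.00805, or adjusted p = 0.993 with an estimated correlation), although their median was −0.01 and their mean 0.03, and the interaction likewise (adjusted p = 0.0147, or adjusted p = 0.993 with an estimated correlation). Of 54 such tests 5 passed with preset correlation, 0 with an estimated correlation, and 2 with fry. Genes that differed between genotypes were spread over the genome. Of 41 called after mock 1 lay on chromosome 5, which carries OsFKBP20-1b, and 0 within 2 Mb of it; of 23 called after ABA 2 lay on chromosome 5 and 0 within 2 Mb. Undescribed genes made up 26 of the 41 and 16 of the 23.

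The tests of other splits and those of the authors' skew were planned before results were seen. The test of endosperm genes was set before its own result, but for libraries already seen to be high in storage transcripts. The splits with the heading number, the tests on iron genes and the other tests on storage transcripts were chosen only after. With 6 libraries per comparison there are 10 splits, too few for a share under 0.05. For ABA in wild type the real split gave 1927 introns and 6625 genes against a highest other of 0 for both, with 1 split as high. For ABA in the mutant it gave 1981 introns and 7298 genes against 0 for both. After mock 3 splits gave as many as the 7 genotype introns, with a highest other of 17, and 1 gave as many as the 41 genes, with a highest other of 1. With the heading number as a term the real split gave 24 introns and 91 genes, and the other 3 splits that part every equal number gave 3 introns and 78 genes at most. After ABA 3 splits gave as many as the 1 genotype intron, with a highest other of 11, and 1 gave as many as the 23 genes, with a highest other of 0. Of 100 drawn splits for the interaction of introns, all 100 gave at least the real 0 calls, with a highest other of 28, but any split gives at least 0, so this says nothing about chance. The authors' rule gave 396, 354, 155 and 240 introns, as many in 3, 4, 7 and 5 of the 10 splits, with highest others of 495, 1173, 471 and 983. Splits calling several times the real count point to a structure of the samples other than genotype and treatment.

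The authors' introns in the ABA-treated mutant were mostly lower, 85.6% against its mock and 85.4% against wild type. The median ratio of intron to exon reads was 32.4% in osfkbp20-1b_ABA_1 but 19.0% and 21.1% in the other 2 libraries, and 23.1% to 33.6% in the other groups. After each ratio was divided by its library median, which takes away a shift of most introns whatever its cause, the lower share was 57.6% against mock and 45.7% against wild type (70.9% in another split of the mutant libraries). Without the division other splits reached 97.9% and 96.3% in 1 direction. They set osfkbp20-1b_mock_1, osfkbp20-1b_mock_2 and osfkbp20-1b_ABA_1, or WT_ABA_1, WT_ABA_2 and osfkbp20-1b_ABA_1, against the remaining libraries. Each side kept most libraries of a real group, so these splits do not decide whether genotype or ABA acted on single introns. A shift of whole libraries is a candidate explanation of the skew, and the division does not separate a technical shift from a real one.

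Of 14 iron acquisition genes 6 were far higher in WT_ABA_1 and osfkbp20-1b_ABA_1 than in other ABA libraries, with NAS1 at 8455 and 2662 reads against 24.8 to 328. Mock libraries labelled as ABA were excluded by LEA medians of 812 or more, against 12.4 at most in mock libraries. A mixture with mock material was excluded because the root marker median, which a mixture would keep at its share or above, was at 9.25% and 6.81% of the mock mean, while NAS1, NAS2, Os02g0650300 and Os11g0134900, the last outside the iron list, were at a median of 48.4% and 17.8%. The other raised iron genes stood at unlike shares of mock. In WT_ABA_1 Os02g0649900 and Os07g0258400 read 10823 and 5922, against at most 8315 and 3742 in WT_mock, while Os02g0306401 read 4812 against at least 6880. The root marker medians gave no sign of more root tissue, at 45.4 or less against 95.2 to 199 in the other ABA libraries. Os03g0107300 read 69.3 and 37.5 against 134 to 508, although 3 of the 8 markers were higher in WT_ABA_1 than in WT_ABA_2 and WT_ABA_3. Most of these markers fell after ABA, so their levels mix tissue content with the ABA response. More root tissue was therefore not excluded. Across genes, which are not independent replicates, the deviations of the 2 libraries correlated at 0.506, so a shared batch of plants or libraries may be involved and stays open.

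Transcripts of 37 seed storage genes were highest in osfkbp20-1b_mock_1, osfkbp20-1b_mock_2 and WT_ABA_1, and 32 of the 37 had exactly these 3 libraries highest. The glutelin gene Os10g0400200 read 4348, 4026 and 4807 in them against 91.8 to 481 elsewhere. Genotype or ABA alone did not account for these levels, because libraries of 1 group differed up to 32.6-fold. A spread within a group cannot exclude that genotype or ABA contributed. The geometric mean of 4 other endosperm genes, without another planned gene that was not among those tested, was 2.20, 2.18 and 1.84 times that of the group's other libraries. In WT_ABA_1 this fell short of the level set beforehand for seed tissue. Single genes did not all follow, with Os03g0796900 at 149.5 in both mutant mock libraries against 142.7 in osfkbp20-1b_mock_3. The library osfkbp20-1b_ABA_1 was highest in this mean (371) with a storage median of 24.1. A rise in the mean therefore does not by itself point to seed tissue. RNA of seed tissue may be the source of the storage transcripts and stays open. Storage genes took 0.350% of a library's reads at most, and reads of another seed library could not be told apart from seed tissue.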
